A study of Macaca mulatta with 4 samples.

How the data were processed

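Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where HIF-1α, the oxygen-regulated subunit of the transcription factor HIF-1, was bound in infarcted heart tissue of male rhesus macaques. Infarction was produced by tying off the left anterior descending coronary artery, and hearts were taken after 6 h or after 4 weeks. Per the labels' protocols, frozen heart tissue was ground, fixed with formaldehyde and homogenised, and protein-DNA complexes were isolated from sonicated nuclei with an antibody. The series holds 4 samples, with 1 ChIP library against HIF-1α and 1 input library (chromatin without antibody) at each time point. Samples were grouped by the time point and the antibody in their labels.

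Per the submitters' processing notes, Bowtie2 2.0 and MACS2 were used; their settings, the MACS2 version, the genome build, any filters and any pooling of animals are not given in the sources used here. The 2 deposited files are peak lists, each made by the authors from the ChIP library against the input of the same time point, per the file names. Each list has 3 columns, the sequence name and the start and end of every called peak, and no score, height, fold enrichment, p-value or summit. Read depth is therefore unknown, and the 2 input samples entered only through the authors' peak calls. How many reads stood behind a list affects how many peaks a caller returns, so peak numbers are not corrected for depth. Peaks were named on chromosomes 1 to 20, X and Y, and on sequences with RefSeq scaffold names, treated here as not placed on a chromosome. Coordinates are given in the build of the files and counted from 1.

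The gene table at hand is of another rhesus assembly, and no genome sequence was used. For that reason peaks were not assigned to genes, and several analyses fixed before the data were examined were not run. These were the share of peaks at promoters, the share with a HIF response element (the RCGTG core site), the genes near peaks, VEGFA among them, and the 8 fixed gene lists (HIF-1 targets, copper handling, angiogenesis, cardiomyocyte, fibroblast and matrix, endothelial and smooth muscle, leukocyte and inflammation, and genes of other tissues). The correlation of peak scores was not run either, and peak width took its place. Under the fixed rule for named items, peaks were to be named by position if genes could not be assigned. With no score to rank by, the 10 widest peaks of each list and the 10 overlapping pairs that ranked widest in both lists were taken, a choice made after the files were seen.

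Overlap was computed with bedtools 2.31.1, and a peak was called shared if at least 1 bp of it lay in a peak of the other list. To give the overlap expected by position alone, the chromosomal peaks of the 4-week list were placed at random 1000 times with their widths kept, either anywhere on the same chromosome or moved by 20 to 500 kb from where they were called. Chromosome lengths were not used; the extent of a chromosome was taken as the largest peak end in either list, which is a lower bound. Shares are given with exact Clopper-Pearson 95% intervals, and densities by distance to the chromosome end with exact Poisson 95% intervals. Where a count was 0, the limit given is that of 3 counts. Intervals and limits cover counting error only and treat peaks as independent, which neighbouring peaks are not. With 1 ChIP library per time point there are no replicates, so no test between time points was made and no p-value is given. Every difference below is between 2 peak lists and has no replicate check.

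Regional grouping, the share near chromosome ends and the widths of overlapping pairs were chosen after the files were seen. A tight cluster was at least 5 peaks of 1 list with gaps of at most 10 kb between neighbours, and clusters within 100 kb of one another on a chromosome were joined into regions. Windows of 1 Mb were compared where they held at least 10 peaks of both lists together, and named where they held at least 30. The scripts were tested on simulated lists of the real sizes. All 200 planted shared peaks and all 30 planted clusters were recovered, and the mean chance overlap of 8.12 peaks over 200 placements stood beside 8.15 by formula. Alternatives fixed before the data were examined were the widest 50% of each list, chromosomes only, isolated peaks only (none within 10 kb), merging within 1 kb, a reciprocal overlap of 50%, and midpoints within 1 kb. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.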

Results

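HIF-1 is a transcription factor of 2 subunits that turns on genes for glycolysis, blood vessel growth and oxygen transport when oxygen is short, and HIF-1α is its oxygen-regulated subunit. The study is about the regulation of HIF-1 activity by copper, and for this it set HIF-1 binding in early infarcted heart beside that in late infarcted heart. The binding data are 1 HIF-1α ChIP-seq peak list from infarcted rhesus heart at 6 h after ligation of the left anterior descending coronary artery and 1 list at 4 weeks, each called against input chromatin of the same time point. The lists carry positions only, so depth and the strength of binding are unknown and peak numbers cannot be set against read numbers.

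The first comparison is the number and extent of called HIF-1α peaks at the 2 time points. The early infarct had 13351 called peaks and the late infarct 7399, a ratio of 1.80. Called peaks covered 4.15 Mb at 6 h and 2.12 Mb at 4 weeks. The typical peak was of similar width, with a median of 261 bp (quartiles 210 and 351 bp) at 6 h and 251 bp (quartiles 210 and 324 bp) at 4 weeks. The narrowest peak was 199 bp in both lists, and 18.1% of 6 h peaks and 15.0% of 4-week peaks had exactly this width. The widest peak was 4523 bp at 6 h and 1181 bp at 4 weeks. The excess at 6 h was smaller among isolated peaks, those with no other peak of the same list within 10 kb, of which there were 9798 at 6 h and 6675 at 4 weeks, a ratio of 1.47. Part of this fall is by construction, since a longer list has more peaks near one another.

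Many peaks lay outside the chromosomes. Scaffolds not placed on a chromosome held 4991 peaks at 6 h, or 37.4% of the list (95% interval 36.6 to 38.2%), and 3264 peaks at 4 weeks, or 44.1% (43.0 to 45.3%). These were spread over 3887 scaffolds at 6 h and 3156 at 4 weeks, of which 540 had peaks at both times. The ratio of 6 h to 4-week peaks was 1.53 on scaffolds and 2.02 on chromosomes. Scaffold peaks were wider than chromosomal ones at 6 h (medians 275 and 254 bp) and narrower at 4 weeks (239 and 260 bp). A single 6 h peak, at positions 770 to 1080, was on a sequence whose name carried no number or letter, and it was left out of the chromosome counts.

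All 20 numbered chromosomes had more HIF-1α peaks at 6 h than at 4 weeks, with ratios from 1.57 on chromosome 20 to 2.55 on chromosome 17. With a ratio of 2.02 over all chromosomes, the direction on each follows from the longer 6 h list. Over these chromosomes the density was 3.08 peaks per Mb at 6 h and 1.53 at 4 weeks. Chromosome 19 was the densest at both times, with 6.57 and 3.81 peaks per Mb, followed by chromosome 16 with 5.34 and 2.85. Chromosome X was sparse, with 114 peaks (0.77 per Mb) at 6 h and 35 (0.24 per Mb) at 4 weeks. The animals were male, and densities are not corrected for the copy number of X and Y. Chromosome Y had 9 peaks at 6 h and none at 4 weeks. At the pooled ratio of the chromosomes, 4.45 peaks would be expected there, and 0 of 4135 chromosomal peaks allows a share of up to 0.0726%. This limit lies below the 0.108% of chromosomal 6 h peaks that were on Y, but it leaves out the counting error of those 9 peaks. The exact 95% interval of the 4-week part of the peaks on Y was 0 to 33.6%, against 33.10% over all chromosomes. With 9 peaks at 6 h this interval could not lie below 33.10% for any 4-week number. Whether Y differs from the other chromosomes was thus not decided with so few peaks.

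The balance between the time points was then compared chromosome by chromosome. Of all chromosomal peaks, 33.10% came from the 4-week list, and the 95% interval of this share missed that value on 4 of 22 chromosomes. Chance would give up to 1.1 if peaks were independent, which clustered peaks are not, so the 4 cannot be read as an excess over chance. The 4-week share was high on chromosome 20 (39.0%, interval 34.7 to 43.4%) and on chromosome 8 (37.2%, 33.14 to 41.3%). The 4-week share was low on chromosome 17 (28.2%, 24.2 to 32.4%) and on chromosome X (23.5%, 16.9 to 31.1%). With the stretches of tight clusters left out of both lists, the share was 38.2% (32.8 to 43.7%) on chromosome 17, an interval that includes the 33.9% over all chromosomes, while those of chromosomes 20 (39.0%, 34.7 to 43.4%), 8 (39.2%, 34.9 to 43.5%) and X (25.2%, 17.8 to 33.83%) still missed it. With isolated peaks only, the intervals of chromosomes 20 (39.7%, 34.8 to 44.6%), 8 (39.6%, 34.9 to 44.5%) and X (27.2%, 19.3 to 36.3%) included the 35.8% over all chromosomes, while that of chromosome 17 (42.8%, 36.8 to 48.8%) lay above it. Both settings take out stretches dense at 6 h, which raises the share on chromosome 17 by construction. How far it rises is not fixed by construction and was not tested, so the higher values there are not read as a reversal.

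**Figure D1:**
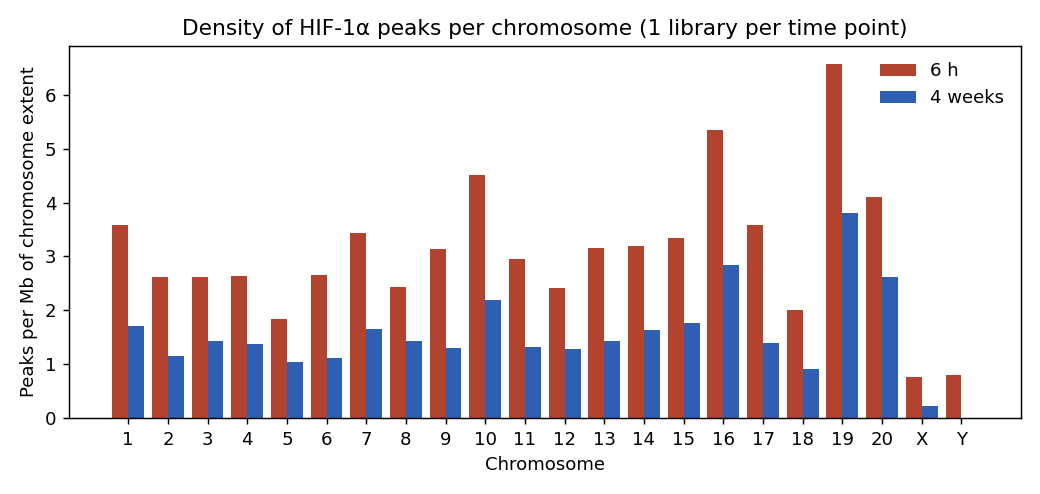
Peaks per Mb of chromosome extent (y axis) on chromosomes 1 to 20, X and Y (x axis), with red bars for 6 h and blue bars for 4 weeks, 1 library each. Every numbered chromosome has the taller bar at 6 h, the time with the longer list. Chromosome 19 is densest (6.57 and 3.81 per Mb), and chromosome Y has no 4-week peak.

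The second comparison is whether the same sites were called as peaks early and late. Few were called at both times: 1221 of the 6 h peaks (9.15%, 95% interval 8.66 to 9.65%) overlapped a 4-week peak, and 1233 of the 4-week peaks (16.7%, 15.8 to 17.5%) overlapped a 6 h peak. The remaining 12130 peaks at 6 h and 6166 at 4 weeks had no counterpart in the other list. The shared part was 0.315 Mb, or 5.29% of all sequence covered by either list. On chromosomes 716 of the 4-week peaks were shared, while 1000 random placements of them on the same chromosomes gave a mean of 8.16 (SD 2.81) and at most 18. Moving each peak by 20 to 500 kb gave a mean of 12.9 (SD 3.56) and at most 23. The observed overlap was thus 87.8 and 55.4 times the mean of these placements. The placements could fall on any position, including sequence to which reads cannot be mapped. On scaffolds 15.8% of 4-week peaks were shared (14.6 to 17.1%), against 17.3% on chromosomes (16.2 to 18.5%), and 449 scaffolds held an overlapping pair.

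Shared sites were the wider ones. The median width of shared peaks was 344 bp at 6 h and 307 bp at 4 weeks, against 256 and 243 bp for peaks called at 1 time only. From the narrowest to the widest 20% of the list, the shared part went from 3.93% (3.23 to 4.74%) to 18.9% (17.4 to 20.4%) at 6 h and from 7.57% (6.27 to 9.03%) to 32.2% (29.9 to 34.7%) at 4 weeks. A wide peak also overlaps by chance more easily than a narrow one. On chromosomes, however, random placement gave means of only 8.16 and 12.9 shared 4-week peaks in all, against 716 observed. These values argue against chance overlap by position as the reason for the rise there. The peaks formed 1243 overlapping pairs with a median overlap of 222 bp. In 757 pairs (60.9%) the 6 h peak was wider, in 475 the 4-week peak was, and the median difference was 31 bp. Across pairs, which are not independent replicates, the 2 widths had a Spearman rho of 0.22. By chromosome, the shared part of 4-week peaks was lowest on chromosome 11 (12.5%, 8.002 to 18.3%) and highest on chromosome X (31.4%, 16.9 to 49.3%, from 11 of 35 peaks), followed by chromosome 20 (23.5%, 17.7 to 30.04%) and chromosome 1 (22.9%, 18.8 to 27.4%). On chromosome 20, 15.3% of 6 h peaks were shared (11.5 to 19.8%).

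**Figure D2:**
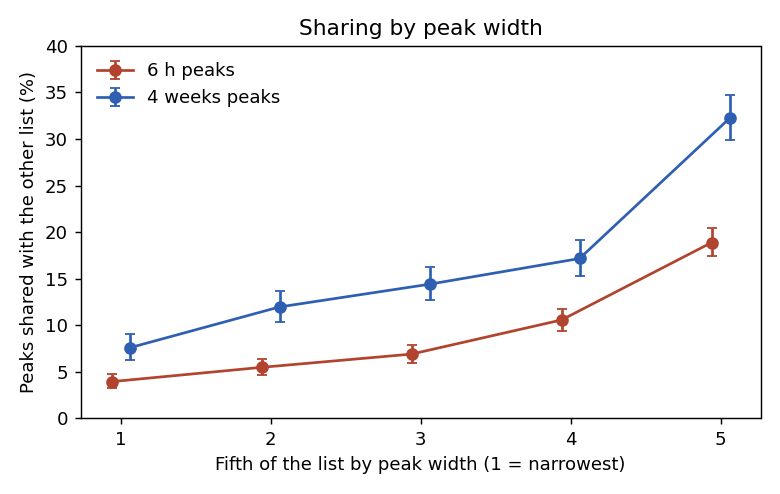
Percentage of peaks that overlap a peak of the other time point (y axis) in steps of 20% of each list by peak width (x axis, 1 is the narrowest); bars are exact 95% binomial intervals, red is 6 h and blue 4 weeks. Sharing reaches 18.9% of 6 h peaks and 32.2% of 4-week peaks in the widest 20% of each list.

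All 10 of the widest 4-week peaks were also called at 6 h. They included peaks on chromosome 16 at 1949429 to 1950609 (1181 bp), chromosome 4 at 171704169 to 171705288 (1120 bp), chromosome 5 at 1973841 to 1974878 (1038 bp), chromosome 6 at 191058 to 192078 (1021 bp), chromosome 7 at 139454837 to 139455850 (1014 bp) and chromosome 19 at 51300032 to 51301024 (993 bp). The other 4 were on scaffolds. Of the 10 widest peaks at 6 h, 8 were on scaffolds and 5 were shared. The other 2 were neighbours on chromosome Y, at 11245315 to 11247845 (2531 bp) and 11248558 to 11251197 (2640 bp), and had no 4-week counterpart. Of the 10 pairs that ranked widest in both lists, the only chromosomal one was on chromosome X, where the 6 h peak spanned 148228776 to 148230395 (1620 bp) and the 4-week peak 148229309 to 148230077 (769 bp). The pair that ranked first was on scaffold NW_014905615, with 2047 bp at 6 h (88 to 2134) and 1088 bp at 4 weeks (143 to 1230). Scaffold NW_015067827 held 3 of the 10 pairs. Genes at these positions were not analysed here.

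The third comparison is how peaks were spaced. At 6 h, HIF-1α peaks were gathered into 93 tight clusters of at least 5 peaks, which held 792 peaks (5.93% of the list, 95% interval 5.54 to 6.35%), while the 4-week list had 4 such clusters with 28 peaks (0.378%, 0.252 to 0.546%). The 6 h clusters had a median span of 11.5 kb, of which peaks covered a median of 25.004%, and 39 lay on chromosomes and 54 on scaffolds. Random placement of the 6 h chromosomal peaks gave at most 1 cluster in 200 placements. In 40 of the 93 clusters the 4-week list had no peak at all, and in the others it had at least 1. With 1.53 4-week peaks per Mb over the numbered chromosomes, most stretches of 11.5 kb would hold none by position alone. The empty clusters are thus no sign of a loss at 4 weeks, and 4-week peaks lay in the clusters on chromosomes more often than by position alone. Of the clustered 6 h peaks 12.1% (9.93 to 14.6%) were shared, against 8.96% of the others, and they were wider (medians 349 and 257 bp).

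Chromosome 17 held the largest clustered regions. Between 8947379 and 9272674, a span of 325 kb with 5 clusters, there were 93 peaks at 6 h and 6 at 4 weeks. A single cluster at 2304582 to 2412362 (108 kb) had 52 peaks at 6 h and 4 at 4 weeks. Chromosome 17 as a whole had 1.40 4-week peaks per Mb, so the 4-week list was dense in both regions as well. The next regions were on chromosome 13 at 103554691 to 103627758 (24 peaks at 6 h, 2 at 4 weeks) and on chromosome 2 at 7097545 to 7159151 (21 and 1). On chromosome 15 at 5075789 to 5142203 there were 15 peaks at 6 h and none at 4 weeks. Of the 4 clusters in the 4-week list, 3 consisted of shared peaks alone. These were at 204830111 to 204840690 on chromosome 1, where all 5 4-week peaks were shared, and on scaffolds NW_015067827 (all 11 shared) and NW_015029120 (all 5 shared). The remaining one, on chromosome 14 at 6954317 to 6983465, had 7 peaks at 4 weeks, of which 1 was shared.

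**Figure D3:**
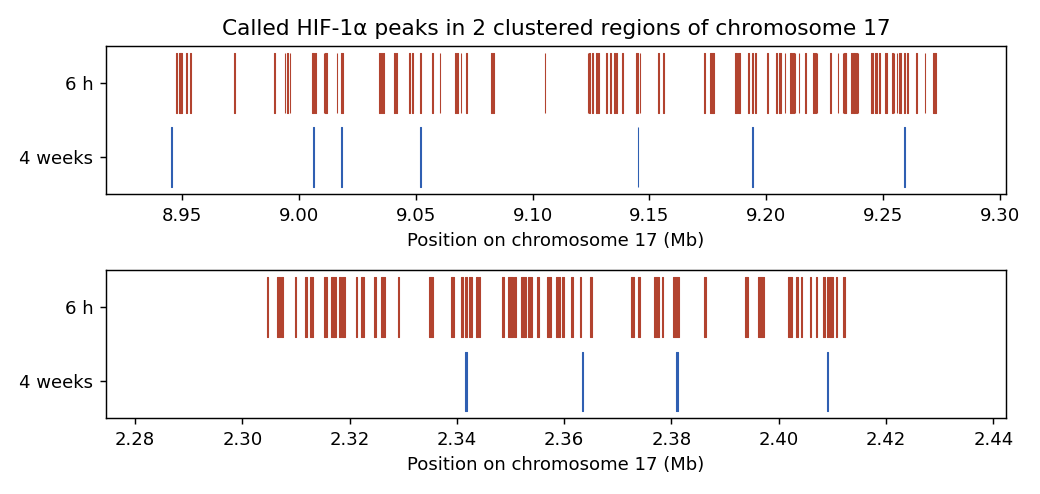
Called peaks (vertical bars, with an outline that widens them beyond scale) at 6 h (red, upper row) and 4 weeks (blue, lower row) along 2 regions of chromosome 17 (x axis, position in Mb). The region from 8947379 to 9272674 holds 93 peaks at 6 h and 6 at 4 weeks, and the one from 2304582 to 2412362 holds 52 and 4.

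The last comparison is where along chromosomes the peaks lay. HIF-1α peaks were dense near chromosome ends at both times, and relatively more so at 4 weeks. Within 2 Mb of an end lay 586 peaks at 6 h, or 7.01% of chromosomal peaks (6.47 to 7.58%), and 446 at 4 weeks, or 10.8% (9.86 to 11.8%), while these stretches made up 3.11% of the chromosome extents. In the last 1 Mb the density was 7.86 peaks per Mb at 6 h (7.06 to 8.74) and 5.66 at 4 weeks (4.98 to 6.41). Farther than 20 Mb from an end it was 2.58 (2.51 to 2.65) and 1.22 (1.17 to 1.27). The far end of each chromosome was taken from its last peak, so it can lie short of the true end.

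In windows of 1 Mb, 10 windows held at least 30 peaks, and 7 of these had more peaks at 6 h. The longer 6 h list alone would give more 6 h peaks in most windows. The windows that start at 9000001 and 2000001 on chromosome 17 had 85 and 53 peaks at 6 h against 7 and 5 at 4 weeks. The first window of chromosome 8 had 39 against 6, the window from 103000001 on chromosome 13 had 35 against 2, and the one from 7000001 on chromosome 2 had 27 against 6. The windows from 1000001 on chromosomes 15 and 19 were closer to even, with 22 against 18 and 18 against 16. More peaks at 4 weeks lay in the window from 143000001 on chromosome 8 (32 against 14 at 6 h), in the first window of chromosome 1 (25 against 15) and in the window from 75000001 on chromosome 16 (23 against 17). Of 304 windows with at least 10 peaks, 15 had relatively more 6 h peaks and 10 relatively more 4-week peaks by the 95% interval of their balance. Chance would give up to 15.2 such windows in all if peaks were independent, which clustered peaks are not. Among them, 8 of the 10 with more 4-week peaks and 2 of the 15 with more 6 h peaks had their midpoint within 2 Mb of an end. Of all 304 windows, 42 did. Across the 2469 windows with a peak, which are not independent replicates, the numbers at the 2 times had a Spearman rho of 0.37. Windows empty in both lists were left out, which can lower this value.

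**Figure D4:**
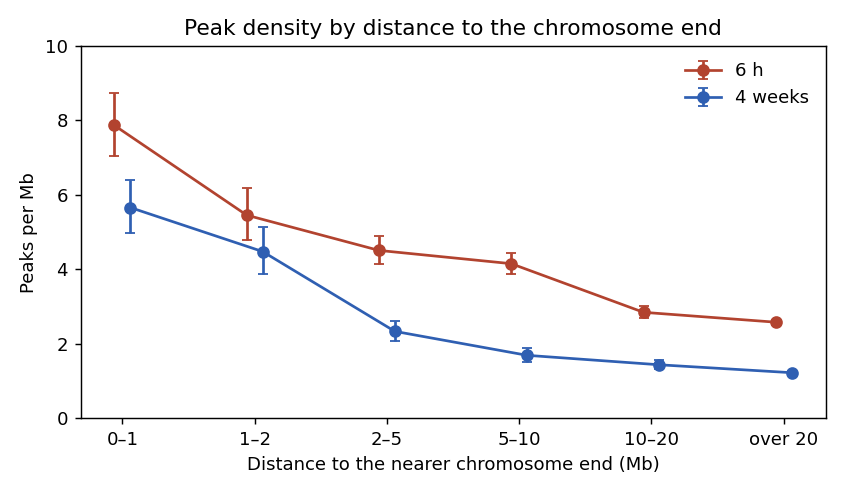
Peaks per Mb (y axis) by distance to the nearer chromosome end in Mb (x axis) at 6 h (red) and 4 weeks (blue); bars are exact 95% Poisson intervals. Density goes from 7.86 to 2.58 per Mb at 6 h and from 5.66 to 1.22 per Mb at 4 weeks.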

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

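Chosen after the files were seen were the results on clusters, chromosome ends and the widths of pairs with all their settings, the alternatives for single chromosomes, all settings by row order or without cluster stretches, the limits on list length, and merging for the shared counts. For peak numbers and shared peaks, the remaining settings were fixed before the data were examined. Of 70 alternative values 30 stayed within the interval of the reported share or within 1.5 times the reported count, and 40 moved. On chromosome 17 the 4-week share passed from below to above that of all chromosomes with cluster stretches left out of both lists (38.2%) and with isolated peaks only (42.8%). Both settings take out stretches dense at 6 h, so a rise there follows from how they are made, but a value above that of all chromosomes does not. With cluster stretches left out the interval (32.8 to 43.7%) includes the 33.9% over all chromosomes. With isolated peaks only it (36.8 to 48.8%) lies above the 35.8% over all chromosomes, and the reason was not tested. The widest 50% of each list by construction held 6675 peaks at 6 h and 3699 at 4 weeks, with 636 shared 4-week peaks. On chromosomes only there were 8359 and 4135 peaks (ratio 2.02), of which 714 at 6 h (8.54%) and 716 at 4 weeks were shared. The ratio of peak numbers was 1.47 with isolated peaks, 1.697 after merging within 1 kb and 1.72 without cluster stretches. Requiring 50% of each peak to be covered left 759 shared peaks, 5.68% of the 6 h list and 10.3% of the 4-week list, while midpoints within 1 kb gave 12.3% and 20.7%. With the 6 h list limited to its widest 7399 peaks the shares were 12.6% and 12.8%, and with its first 7399 rows 12.2% and 12.3%. The first 50% of the rows of each list had 552 shared 4-week peaks, 8.19% and 14.9%, and leaving cluster stretches out of both lists gave 15.5% of 4-week peaks. Clusters at 6 h numbered 361 with at least 3 peaks, 19 with at least 10 and 39 on chromosomes only. At 4 weeks they numbered 43, 1 and 2 under these settings, 2 with gaps to 5 kb and 11 with gaps to 20 kb, where 6 h had 103. The share within 2 Mb of an end was 8.54% at 6 h and 12.07% at 4 weeks in the first 50% of the rows, 6.15% and 8.51% among isolated peaks, and at 4 weeks 12.14% in the widest and 9.16% in the narrowest 50%. The cause of these moves was not tested beyond the smaller lists that the settings make. The planned limit of the longer list by score, and all alternatives for promoters, HIF response elements, genes and gene lists, were not run. No paired analysis was possible because each time point has 1 ChIP library. Depth is unknown, so it cannot be said how many 4-week peaks were missed for lack of reads.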

Other observations

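The tests below were added after the patterns they address were seen; for the 2 on chromosome ends, what they predict was written before their own values were seen. With 1 library per time point, time after infarction cannot be separated from the library and the animal or animals behind it, and a difference between early and late infarct stays open, untested, in each case.

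The 6 h list had 93 tight clusters of peaks and the 4-week list 4. The longer list alone is argued against, since 1000 random thinnings of the 6 h list to the length of the 4-week list kept between 19 and 42 clusters. Repeat copies gathered on unplaced scaffolds are also argued against as the whole cause, since 39 of the 6 h clusters were on chromosomes, against 2 at 4 weeks. A copy number difference between the 6 h ChIP and its input over whole stretches, for example from different animals, may give such runs of peaks. Peaks covered a median of 25.004% of a cluster, which is neither the near-complete cover nor the isolated sites that would decide it, and read coverage would be needed.

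Most 4-week peaks (83.3%) lay where the 6 h list had none. The 4-week list cannot be a thinned copy of the 6 h list, since every peak of such a copy would be shared. The number of tight clusters, at least 19 in random thinnings and 4 at 4 weeks, does not bear on the unshared peaks. Calls near the threshold that come and go by chance are a candidate explanation: sharing was lowest in the narrowest peaks. The widest 20% of the 4-week list was still only 32.2% shared, and without scores or a second library at either time this cannot be told apart from sites bound at 1 time only.

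Peaks at 4 weeks lay within 2 Mb of a chromosome end more often than peaks at 6 h (10.8% and 7.01%). The tight clusters in the 6 h list are too few to account for it, as they held 385 of the 8359 chromosomal 6 h peaks. With cluster stretches left out of both lists the shares were 10.9% and 6.97%. So few peaks could not have closed the gap wherever they lay, so this setting decided nothing further. Nor was the difference a matter of wide peaks only: in the narrower 50% of each list the shares were 9.16% (7.89 to 10.6%) at 4 weeks and 6.76% (6.03 to 7.53%) at 6 h. Base composition and gene density near the ends were not examined, and may differ in effect between libraries.

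The rows of both files are not in genomic order. They fall into 1083 runs sorted by position at 6 h and 452 at 4 weeks, the longest of 1751 and 1129 rows. In the first 10% of the rows 21.6% of 6 h peaks (19.4 to 23.9%) and 34.5% of 4-week peaks (31.0 to 38.0%) were shared, against 3.37% (2.47 to 4.48%) and 10.7% (8.54 to 13.1%) in the last 10%. The first 10% of rows was mostly scaffold peaks, 82.9% at 6 h and 86.1% at 4 weeks, against 42.1% and 23.5% in the last 10%. A hypothesis drawn from this is that rows are ordered by a measure of peak strength with many ties. Widths do not decide it: the median in the first and last 10% of rows was 323 and 273 bp at 6 h, but 241 and 268.5 bp at 4 weeks, against what such an order may be expected to give. The hypothesis stays open, and the row order entered only the alternative settings that name it.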
